A study of Mus musculus with 3 samples.

How the data were processed

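Chromatin carrying H3K27me3, the trimethylated form of lysine 27 of histone H3 that Polycomb proteins lay down at repressed genes, was measured in colonic epithelial cells of male BALB/c mice by immunoprecipitation and hybridisation to a 2-colour Agilent CpG island tiling array. Per the labels, each of the 3 arrays held a pool of 3 mice: untreated at 7 weeks of age, untreated at 23 weeks, or 23 weeks old after 2% DSS (dextran sulfate sodium, a polymer that damages the colonic epithelium) given for a week from the age of 7 weeks. Crypts were isolated and cross-linked before sonication. Per the labels, the immunoprecipitate was labelled with Cy5 (red) and whole-cell extract, the input, with Cy3 (green) on all arrays, so the red over green ratio measured enrichment and no dyes were swapped.

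The scanner files held spot intensities that the authors had extracted with Agilent Feature Extraction, version 10.7.3.1 per the file headers and version 9.1 per the submitters' processing notes. The processed intensity of each channel was background-subtracted and dye-normalised with a linear factor per dye, per the file headers. The deposited log10 ratio equalled the log10 of the red over green processed intensities within 0.001 at 100% of probes on each array, rounded to 3 digits. A deposited table for the whole series held a linear ratio per positioned probe with a median of 1 on each array. Its direction was that of red over green, since its log2 values correlated with the same array's scanner ratios at r = 0.81 (7 weeks), 0.82 (23 weeks) and 0.79 (DSS) over probes. The best value with another array was 0.78, 0.80 and 0.78. They correlated more closely, at 0.88, 0.89 and 0.86, with the mean of scanner ratios over probes within 300 bp, and how the authors made this table is not given in the sources used here. The table served as an alternative.

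Each array had 103601 spots, of which 4914 were positive and 1036 negative controls, and 97651 probes with a median length of 45 bases. Of these, 442 had no position in the files, 50 lay on unplaced sequence and 97159 on 20 assembled chromosomes. The files name no genome build. Probes lay beyond the last gene of the GRCm38 gene table on 7 of these chromosomes, so that table was not used and coordinates are given as the array files state them. The files pair no probe with a gene name, and genes, exons and introns are therefore not named.

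Starting from the processed intensities, log2 of red over green was taken per probe. Control spots and 592 probes with a non-uniformity or population outlier flag in either channel of any array were left out, as were 5976 probes not well above background in both channels on all 3 arrays. Nearly all flags came from 1 array: over all probes, positioned or not, 585 had a flag in untreated mice at 23 weeks, 2 at 7 weeks and 7 after DSS. The remaining 90591 probes were centred on each array's median, with no loess or quantile step, because many probes carry signal. Probes whose starts lay within 500 bp of the previous start were joined, and regions with at least 3 kept probes took the median of their probes. This gave 13713 regions with a median of 5 probes (3 to 41) and a median length of 638 bp, holding 88449 probes. A region with a value of at least 1, a 2-fold enrichment over the array's median probe, was called marked. A difference between arrays was taken per probe and then as the median over the region. A region was called gained when this difference was at least 1 and its later or treated value at least 1, and lost when the difference was at most -1 and its earlier or untreated value at least 1.

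With 1 array per group there is no replicate error, no p-value across regions is reported, and the differences have no replicate check. The SD printed with a region's value is the spread of its probes within 1 hybridisation. The number of arrays limits the precision. Each array was on a slide of its own and scanned on a day of its own, so slide, scan and group cannot be told apart.

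The comparisons, the region rule, the thresholds and the alternatives were fixed before the data were examined. The main comparisons were untreated mice at 23 against 7 weeks and DSS against untreated mice at 23 weeks. DSS at 23 weeks against untreated at 7 weeks, which differs in age and treatment at once, was supporting. Regions were named by a fixed rule: in each main comparison the 8 gained and 8 lost regions of largest difference with at least 4 probes and 80% of probes changed the same way. The rule also allowed counts of 5 or fewer to be named in full. It asked for a gene name too, a condition that was dropped. Regions named outside the rule were chosen after their values were seen, and the text says so. The 15 gene lists and the reference genes fixed beforehand were not analysed here, because no probe has a gene name.

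Alternatives were normexp background correction (offset 50) on the median spot and background intensities, since the files hold no mean green signal, the deposited ratio table, scaling to a common interquartile range, quantile normalisation, loess within each array (span 0.3, 4 iterations), a background filter on the input alone, no background filter, at least 5 probes per region, gaps of up to 1000 bp, the mean of probes, and thresholds of 1.5 and 0.58. Shuffles of the probes' residuals, 100 per setting and within 20 levels of signal, kept each array's trend with level. They gave the counts to be had from that trend together with single-probe noise. The region calls were tested on simulated data for DSS against untreated mice at 23 weeks, with 200 of 13713 regions lowered. The rule recovered 95 of 100 regions lowered by 1.5 and 99 of 100 lowered by 2, with 4 calls among the 13513 unchanged regions. The simulated arrays shared a common ratio range and had independent noise per probe. The real arrays differed in range, so these rates do not carry over to them. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for normexp and loess.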

Results

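H3K27me3 was compared at CpG islands of mouse colonic epithelium at 2 ages and after DSS colitis, with 1 array, made from a pool of 3 mice, for each of the 3 groups. The median background-subtracted intensity of the immunoprecipitate was 475 at 7 weeks, 120 at 23 weeks and 268 after DSS, and that of the input was 537, 217 and 492. Of 97651 probes, 2387, 4949 and 3781 were not well above background in the immunoprecipitate, and none was saturated. All values below are log2 ratios of immunoprecipitate over input relative to the array's median probe, and ± gives the SD over a region's probes in a single hybridisation, since no group had a replicate.

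Most regions marked at 7 weeks or after DSS were also marked in untreated mice at 23 weeks, before and after the arrays were scaled to a common range. Of 13713 regions, 2605 (19%) were marked in untreated mice at 7 weeks, 3321 (24.2%) in untreated mice at 23 weeks and 1708 (12.5%) after DSS. A total of 1641 regions were marked on all 3 arrays and 10342 on none. Of the regions marked at 7 weeks, 2568 (98.6%) were also marked at 23 weeks, and of those marked after DSS 1693 (99.1%) were marked in untreated mice of that age. Before scaling, 35 regions were marked at 7 weeks alone and 13 after DSS alone, while 701 were marked at 23 weeks alone. Across regions, which are not independent replicates, the 7-week array correlated with the 23-week array at r = 0.957 (rho = 0.950) and with the DSS array at r = 0.955 (rho = 0.951), and the arrays of 23-week-old mice correlated at r = 0.940 (rho = 0.937). The arrays differed in their spread: the interquartile range of probe log2 ratios was 1.81 at 7 weeks, 2.37 at 23 weeks and 1.42 after DSS. When the arrays were scaled to a common range, 2691, 2798 and 2494 regions were marked, and 2195 on all 3. The regions marked on a single array then numbered 119 at 7 weeks, 181 at 23 weeks and 130 after DSS, and 93.3% of those marked at 7 weeks and 92.3% of those marked after DSS were marked in untreated mice at 23 weeks.

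**Figure D1:**
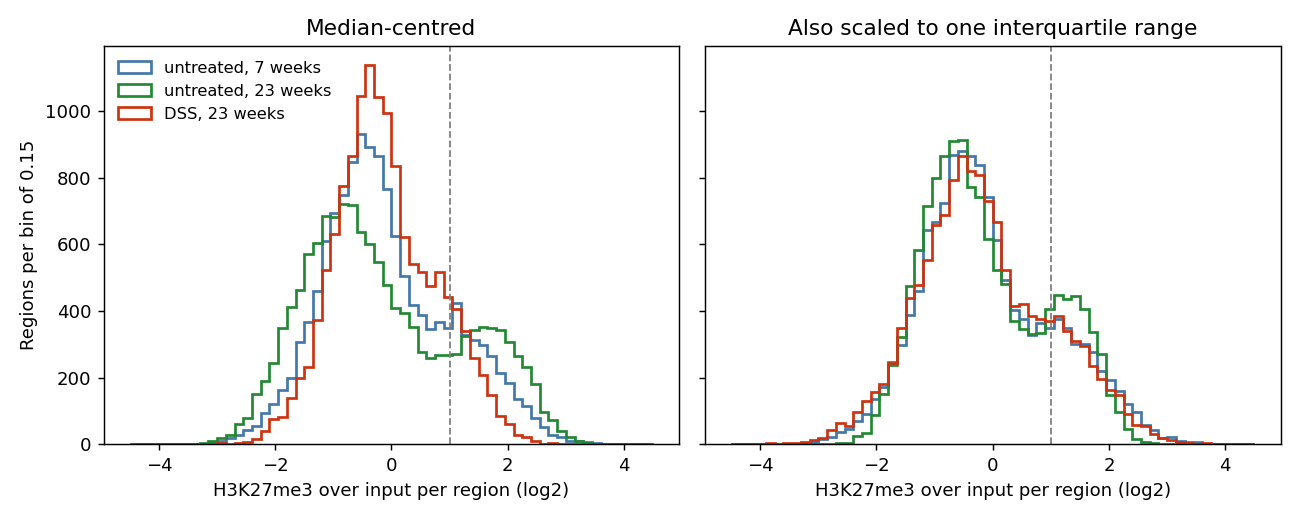
Number of regions (y axis, per bin of 0.15) by H3K27me3 over input (x axis, log2) on the 3 arrays, median-centred (left) and also scaled to a common interquartile range (right), with the threshold of 1 dashed. The DSS array had the narrowest distribution and 1708 marked regions against 3321 for untreated mice of 23 weeks, and 2494 against 2798 after scaling.

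Regions marked in every group lay singly or next to others, and how far this follows the placement of regions on the array was not tested. Joined over distances of up to 20 kb, a distance chosen after the data were seen, the 1641 regions formed 1230 clusters, of which 970 held a single region and 36 held at least 4. The cluster with most regions, 9, lay on chromosome 15 from 102749463 to 102810397 and had median values of 2.13 ± 0.55 at 7 weeks, 2.40 ± 0.42 at 23 weeks and 1.44 ± 0.63 after DSS (SD over its regions). Clusters of 7 regions lay on chromosome 19 from 44770721 to 44812736 (1.90 ± 0.42, 2.48 ± 0.31 and 1.64 ± 0.32) and on chromosome 2 from 74528074 to 74564736 (2.24 ± 0.45, 2.45 ± 0.32 and 1.65 ± 0.44). A neighbouring cluster of 5 regions on chromosome 2, from 74475969 to 74493745, had 1.74 ± 0.26, 1.53 ± 0.17 and 1.51 ± 0.10. Its median difference between DSS and untreated mice at 23 weeks was 0.02, against -0.77 in the cluster of 7 on that chromosome. After scaling these differences were 0.80 and 0.42. Chromosome 2 had the highest share of marked regions at 7 weeks (24.6% of 1149, Wilson 95% interval 22.2% to 27.2%). The lowest shares were on chromosomes 16 (12.7% of 411, 9.78% to 16.2%) and X (12.7% of 371, 9.66% to 16.4%), and the intervals cover counting error only.

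**Figure D2:**
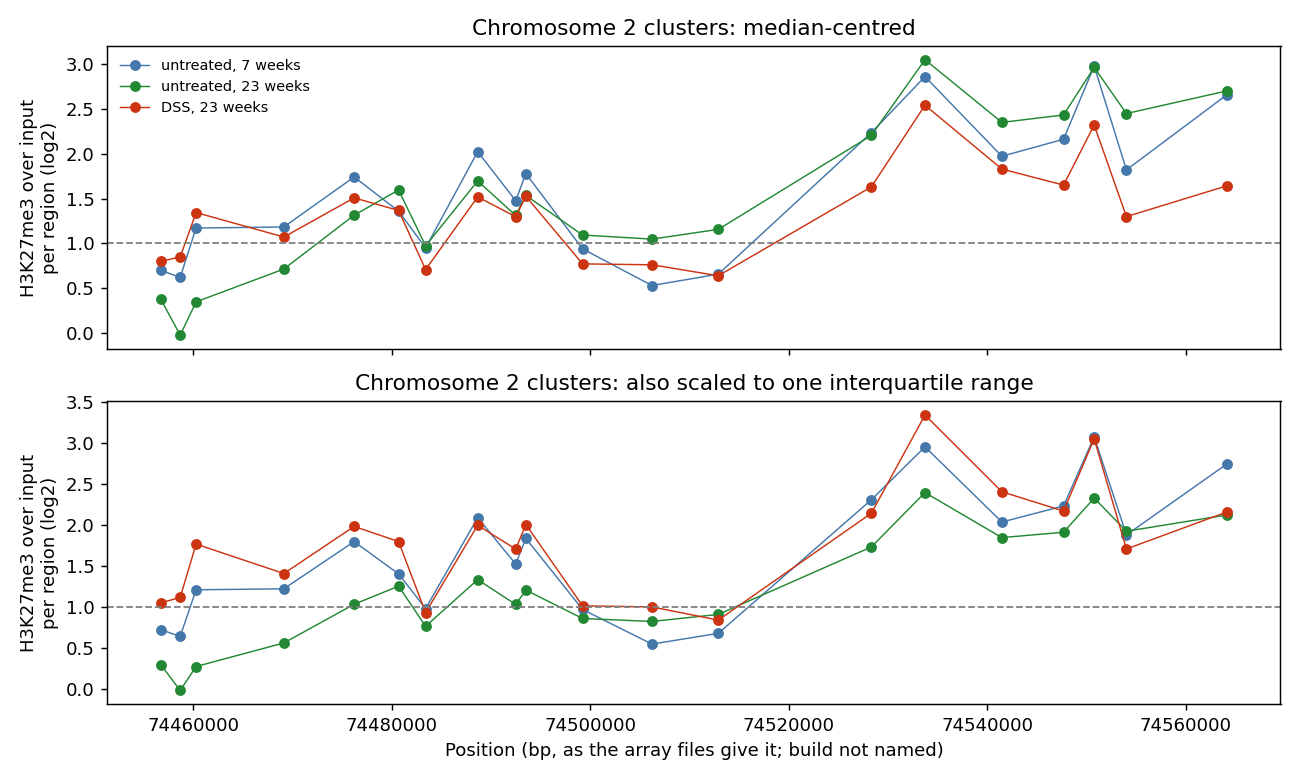
H3K27me3 over input (y axis, log2, median per region) along chromosome 2 (x axis, bp as in the array files) on the 3 arrays, median-centred (top) and also scaled to a common interquartile range (bottom), with lines joining neighbouring regions. In the cluster from 74528074 to 74564736 the DSS values lay below those of untreated mice at 23 weeks before scaling (median difference -0.77). In the cluster from 74475969 to 74493745 the median difference was 0.02, with medians of 1.53 in untreated mice at 23 weeks and 1.51 after DSS.

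Few regions differed between untreated mice of 7 and 23 weeks. At the threshold of 2-fold, 6 regions were gained and 1 was lost with age. The gained regions that the rule named lay on chromosome 7 from 11703535 to 11703902 (4 probes), chromosome 18 from 25896076 to 25896658 (5 probes) and chromosome 2 from 173228384 to 173229867 (11 probes). On chromosome 7 the value was 0.02 ± 0.60 at 7 weeks and 1.20 ± 0.42 at 23 weeks, a difference of 1.14 ± 0.26. On chromosome 18 it was 0.78 ± 0.76 and 1.84 ± 0.60 (difference 1.08 ± 0.27), and on chromosome 2 it was 0.03 ± 0.68 and 1.18 ± 0.52 (1.03 ± 0.56). The DSS array, also from mice of 23 weeks, had -0.06 ± 0.34 on chromosome 7, 1.34 ± 0.60 on chromosome 18 and 0.69 ± 0.38 on chromosome 2. Only the region on chromosome 18 was therefore marked there. The lost region had 3 probes, too few for the ranking by size, and was named because the rule allowed counts of 5 or fewer to be named in full. It lay on chromosome 2 from 56926962 to 56927566. It had 2.05 ± 0.62 at 7 weeks, 0.91 ± 0.36 at 23 weeks and 0.02 ± 0.16 after DSS. The median region marked at either age was higher by 0.29 at 23 weeks, but this turned to -0.14 with scaling, and the calls turned from 6 gained and 1 lost to 0 and 13 with scaling, 0 and 2 with quantile normalisation, 0 and 3 with normexp and 3 and 4 with loess. None of the regions called with loess was among those called before, and the named gains had 0.31, 0.10 and 0.55 with it. Gains were instead more numerous in the deposited ratio table (31 gained, 2 lost) and with the input filter alone or no background filter (11 gained, 0 lost in both). Shuffled probes, which kept each array's trend with level, gave a mean of 11.1 lost regions (3 to 19) against the 13 with scaling. They gave a mean of 1.02 gained (0 to 3) against the 6 without scaling.

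Whether colitis at 7 weeks left a different H3K27me3 pattern at 23 weeks was addressed by DSS-treated against untreated mice of 23 weeks. Regions carrying the mark were lower after DSS: 293 were lost and 1 was gained. The 293 regions had a median of 1.56 at 7 weeks, 2.04 in untreated mice at 23 weeks and 0.86 after DSS, with a median difference of -1.10, and 115 of them still passed the threshold for a mark after DSS. Most of these calls did not hold when the arrays were brought to a common range. After scaling to a common interquartile range 16 regions were lost, all among the 293, and 15 were gained. Quantile normalisation gave 18 lost, all among the 293, and 13 gained. Loess within each array gave 18 lost, of which 5 were among the 293, and 2 gained, neither of them the region gained before. Normexp, which sets no common range, gave 30 lost, all among the 293, and 1 gained. Losses were instead more numerous in the deposited ratio table (619), with the input filter alone (467) and with no background filter (468). After scaling the 293 regions, which had been chosen for a large difference between these same arrays, had a median difference of -0.42. The median difference over all regions marked on either array was -0.70 before scaling and 0.04 after it. Scaling and quantile normalisation remove a difference in range whatever its source. They therefore cannot tell a general loss of H3K27me3 from a difference between arrays.

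**Figure D3:**
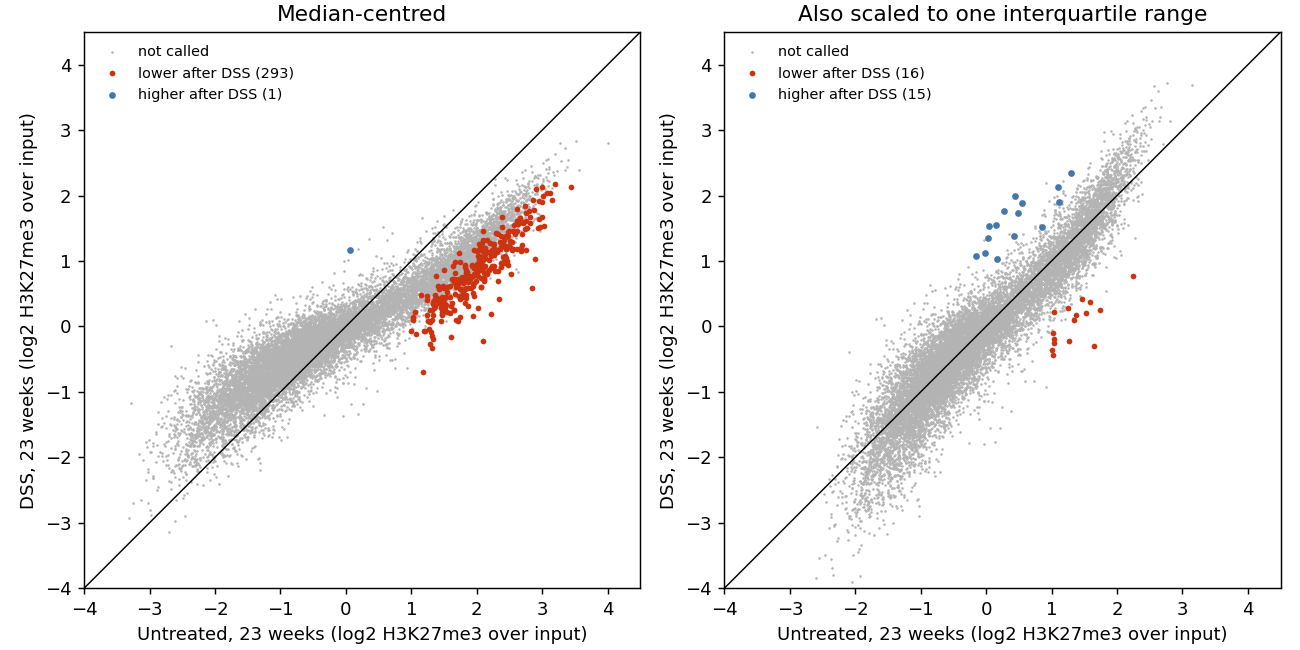
H3K27me3 over input per region (log2) in untreated mice of 23 weeks (x axis) and after DSS (y axis), median-centred (left) and also scaled to a common interquartile range (right), with regions lower after DSS in red, higher in blue and all others in grey. The points lie along a slope shallower than the line of equality on the left, where 293 regions were lost and 1 gained, and the counts were 16 and 15 on the right.

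The 8 regions with the largest loss after DSS under the naming rule had marks in both untreated groups. After DSS their values lay between -0.23 and 0.31, except on chromosomes 17 (0.80) and 2 (1.51, still marked). On chromosome 5, from 147584860 to 147585285, all 5 probes were lower, with 1.84 ± 0.46 at 7 weeks, 2.09 ± 0.29 at 23 weeks and -0.23 ± 0.41 after DSS, a difference of -2.32 ± 0.53 (-1.95 after scaling). A neighbour on the same chromosome, from 147580464 to 147581088, went from 1.61 ± 0.54 to -0.16 ± 0.48 (difference -1.77 ± 0.96, 5 of 5 probes). On chromosome 11, from 102896187 to 102896708, H3K27me3 was 2.31 ± 0.41 at 7 weeks, 2.22 ± 0.26 at 23 weeks and 0.19 ± 0.15 after DSS, 3.92-fold lower, with a difference of -1.97 ± 0.13. Another neighbouring pair lay on chromosome 10, from 126567844 to 126569164 (12 probes) and from 126573491 to 126574244 (8 probes). Every probe of both was lower, with differences of -1.61 ± 0.58 and -1.75 ± 0.29. The rule also named chromosome 5 from 135326499 to 135326931 (-1.72 ± 0.42), chromosome 17 from 68741668 to 68742501 (-1.64 ± 0.42) and chromosome 2 from 123781310 to 123782254 (-1.55 ± 0.19). After scaling these last 3 had differences of -1.15, -0.66 and -0.42, so those on chromosomes 17 and 2 no longer passed. Loess within each array brought all 8 but the first on chromosome 5 above -1. Loess fits the ratio against the mean intensity of both channels, which enrichment raises, and so can take out part of the enrichment. With it fewer regions were marked on every array (2151 at 7 weeks, 2097 in untreated mice at 23 weeks and 1546 after DSS).

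**Figure D4:**
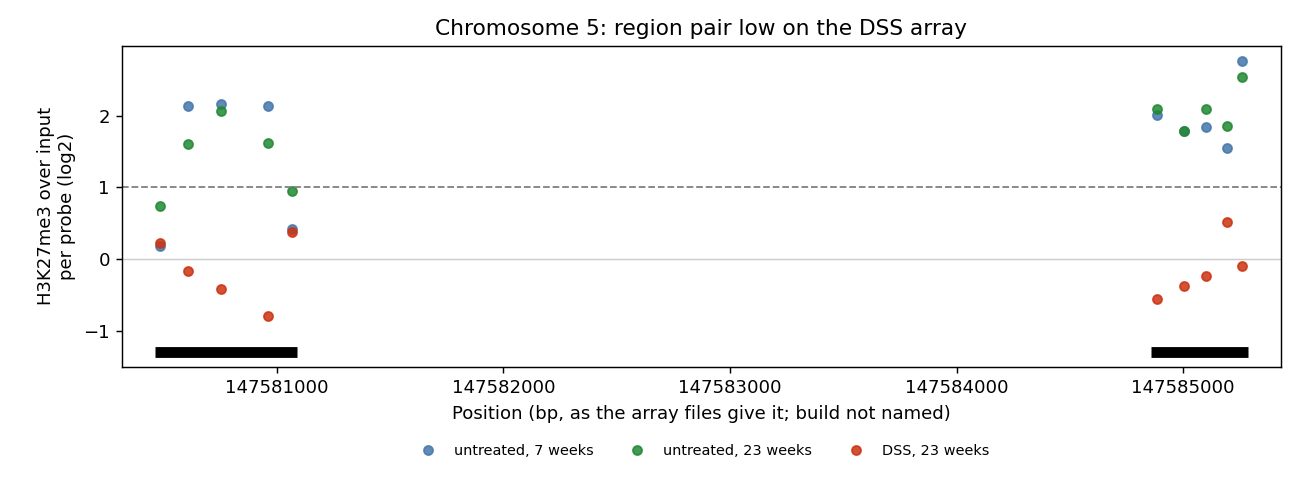
H3K27me3 over input (y axis, log2, a point per probe) at the pair of regions on chromosome 5 (x axis, bp as in the array files) on the 3 arrays, with the regions as black bars and the threshold of 1 dashed. In the region from 147584860 to 147585285 all 5 probes were lower after DSS (-0.23 against 2.09 in untreated mice of 23 weeks, medians).

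The gained region after DSS lay on chromosome 4 from 53180805 to 53181379. It had no mark in untreated mice (0.02 ± 0.41 at 7 weeks and 0.06 ± 0.64 at 23 weeks) and 1.16 ± 0.39 after DSS, a difference of 1.28 ± 0.91 over 5 probes, of which 4 were higher. The call was lost with loess (0.90) and with the mean of probes (0.98). With scaling, 14 further regions were gained, and shuffled probes gave a mean of 2.83 gains (0 to 8) against these 15 in all. A pair of them, chosen after their values were seen, lay on chromosome 2 from 74458432 to 74458925 and from 74459810 to 74460750, next to the cluster of 5 described above. Before scaling they had -0.03 ± 0.39 and 0.35 ± 0.51 in untreated mice at 23 weeks, 0.85 ± 0.24 and 1.34 ± 0.26 after DSS, and 0.62 ± 0.52 and 1.17 ± 0.66 at 7 weeks.

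DSS-treated mice at 23 weeks also had lower values than untreated mice at 7 weeks, with 75 regions lost and 1 gained, the gained region on chromosome 4. With scaling 35 were lost, 32 of them among the 75, and 13 gained, and with quantile normalisation 25 and 14. Loess gave 15 lost, all among the 75, and 0 gained. Normexp gave 76 lost, 61 of them among the 75, and 1 gained, although it left 30 losses against untreated mice at 23 weeks. The cause of that contrast was not tested. Of the 293 regions lost against untreated mice at 23 weeks, 46 were also lost against 7 weeks. Lists drawn independently from all 13713 regions would share 1.60. An excess over that was set in advance, because a loss needs a mark on the untreated array and both untreated arrays marked largely the same regions. Shuffled probes, which keep the levels of the regions and the shared DSS array, shared a mean of 7.26 (2 to 16). After scaling 6 regions were lost in both comparisons, against 0.041 for independent lists and 0 in every shuffle. The value for independent lists is too low here for the same reason. Part of the excess over the shuffles may come from the shared DSS array. Besides the pair on chromosome 5 and the region at 102896187 on chromosome 11, these were chromosome 13 from 34137707 to 34138100 (3 probes, 2.51 ± 1.03 at 7 weeks, 2.85 ± 0.48 at 23 weeks and 0.59 ± 0.40 after DSS), chromosome 4 from 127473771 to 127474175 (1.32 ± 0.46, 1.32 ± 0.34 and -0.14 ± 0.67) and chromosome 11 from 5801958 to 5802375 (1.45 ± 1.45, 1.59 ± 0.84 and 0.21 ± 0.70), named after their values were seen. With loess, the loss against untreated mice at 23 weeks fell short of the threshold on chromosomes 4 (-0.52) and 11 at 5801958 (-0.54). It also fell short with loess on chromosome 11 at 102896187 (-0.94) and on chromosome 5 at 147580464 (-0.75). With normexp it fell short on chromosome 4 (-0.96). Scaled gains shared by both comparisons numbered 10, against 0.014 for independent lists and a mean of 0.04 in shuffles. Here too the shared DSS array may add to the excess. A gain in either comparison needs a mark on that array, so the value for independent lists is again too low. Of these 10, only the region on chromosome 4 at 53180805 was also gained before scaling. Their differences from untreated mice at 23 weeks before scaling ran from 0.26 to 1.28.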

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

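The tests of input, of ratio range, of slide and scan and of neighbouring positions below were chosen after the values they rest on had been seen, and the shuffles were planned before their result. Among the 442 probes without a position, which no comparison used, 396 passed the filters on background and non-uniformity. The population outlier flag, which was applied to positioned probes, was not applied to them. Of the 396, 1 was marked after DSS and higher by at least 1 than on both untreated arrays, a value in data outside the main measurement. Its values were -0.27 at 7 weeks, -0.10 at 23 weeks and 1.05 after DSS. Of the 90591 positioned probes, 52 (0.0574%) met the same condition. The opposite, marked on both untreated arrays and lower by at least 1 after DSS, held for 3 of the 396 probes and for 1235 (1.36%) of the positioned probes.

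Marked regions had lower values on the DSS array, with 293 regions lost. Over these 293, chosen for their ratio difference, the median input difference was 0.044 ± 0.36 (SD over regions) and that of the immunoprecipitate -1.18. This argues against a common shift of their input. It cannot exclude a share of the input in the ratio range, since the interquartile range of log2 input was 1.45 on the untreated 23-week array and 1.93 after DSS. A difference in ratio range, narrower on the DSS array or wider on the untreated 23-week array, is a candidate explanation: the 2706 regions at or below -1 at 7 weeks, an array outside the comparison, were higher after DSS by a median of 0.37 ± 0.32, which a loss limited to marked regions would not give. Regions at or below -1 on the array outside each comparison were lower at 23 than at 7 weeks by a median difference of -0.16 and higher after DSS than at 7 weeks by 0.15, so these values single out neither array. In the input, though, the DSS array correlated over probes at r = 0.983 with the 7-week array and at 0.911 with the untreated 23-week array. In the immunoprecipitate these values were 0.974 and 0.923. Shuffled probes that kept each array's trend with level gave a mean of 105 lost regions (85 to 138), part of the 293, and whether the rest comes from that trend stays open because probes of a region may share errors. The 3 arrays were on 3 slides and scanned on 3 days, so slide, scan and an effect of DSS, which was not tested separately, cannot be told apart.

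The 16 regions lower after DSS once the arrays were scaled were weighed in the same way. Shuffled probes gave a mean of 0.18 such regions (0 to 1), which argues against independent noise of single probes. The median input difference over the 16 was -0.079 ± 0.31 and that of the immunoprecipitate -1.89, which argues against the input. Of the 16, 4 lay within 50 kb of another, the pairs on chromosomes 5 and 10, and 8 of 10000 draws of regions of like level held as many (mean 0.0748), which decides nothing about their positions because the pairs had prompted the count. A local loss of H3K27me3 after DSS and a difference between slides, scans or pools both stay open, and neither was tested.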

How the results depend on the processing

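Alternatives were run 1 at a time, all planned before the data were examined. Of 120 counts, 63 stayed within 1.5 times the main count and 57 did not. With age (6 gained, 1 lost), the gained and lost counts were 0 and 3 with normexp, 31 and 2 in the deposited ratio table, 0 and 13 with interquartile scaling, 0 and 2 with quantile normalisation, 3 and 4 with loess, 11 and 0 with the input filter alone and with no background filter, 2 and 0 with at least 5 probes, 0 and 0 at the threshold of 1.5 and 378 and 16 at 0.58; the mean of probes gave 0 lost. After DSS (1 gained, 293 lost), normexp gave 30 lost, the deposited ratios 3 gained and 619 lost, scaling 15 and 16, quantile normalisation 13 and 18, loess 2 and 18 (0 and 5 of them called in the main setting), the input filter alone 467 lost, no background filter 468 lost, at least 5 probes 184 lost, the threshold of 1.5 gave 0 and 12 and that of 0.58 gave 18 and 2626; gaps of up to 1000 bp gave 2 gained and the mean of probes 0 gained. Against 7 weeks (1 gained, 75 lost), scaling gave 13 and 35, quantile normalisation 14 and 25, loess 0 and 15, at least 5 probes 43 lost, the threshold of 1.5 gave 0 and 10 and that of 0.58 gave 32 and 842. Marked regions moved to 2578 after DSS with quantile normalisation and to 2097 at 23 weeks with loess. At the threshold of 1.5 they were 1426 at 7 weeks, 564 after DSS and 552 on all 3 arrays, and at 0.58 they were 3067 after DSS and 2911 on all 3. Fewer regions enter with at least 5 probes and more probes without the background filters. Thresholds act by construction, and interquartile scaling and quantile normalisation remove a difference in range by construction. The offset of normexp narrows ratios by construction, most at low intensities, and loess can take out part of the enrichment. How much of their changes this makes was not tested, nor was the cause for the other settings. Of 291 values of named regions under alternatives, 227 moved by less than the SD over probes and 64 by more. Of these values 287 kept the sign. The other 4, all of a region on chromosome 8 that the main setting did not call, lay near 0. The floor of 5 probes cannot move these values, and the wider gap and the background filters moved most of them little or not at all. These settings raise the tallies given here while testing the values little. The region at 147584860 on chromosome 5 was at or below -1 in all 11 settings in which it was computed, the main one included (-2.46 to -1.04), and the one at 34137707 on chromosome 13 in all 10 in which it could be formed. Signal over background limits the untreated 23-week array most, with 4949 probes not well above background in the immunoprecipitate. That array also had most of the outlier flags, at 585 probes against 2 at 7 weeks and 7 after DSS. Centring on housekeeping genes, the gene lists and their alternatives were not run, because no probe has a gene name. No paired analysis was possible because each group had 1 array.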

Other observations

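The test on the X chromosome below was chosen after its result was seen. Before scaling, the X chromosome had few marks at 7 weeks and after DSS and a share at 23 weeks close to the 24.2% of all regions: 12.7% of its 371 regions were marked at 7 weeks, 22.1% at 23 weeks (Wilson 95% interval 18.2% to 26.6%) and 7.01% after DSS (4.83% to 10.1%). The median X region was higher at 23 than at 7 weeks by 0.10, and by 0.08 after scaling, while autosome medians ran from -0.05 to 0.02 and from -0.03 to 0.02. On X the input stood outside the autosomes and the immunoprecipitate did not, each channel centred on its array median: the median X input difference, 23 minus 7 weeks, was -0.25 ± 0.35 (SD over regions), with lower input in 277 of 371 regions, against autosome medians of -0.05 to 0.00. The immunoprecipitate differed by -0.02 on X and by -0.05 to 0.13 on the autosomes. The input of the DSS array differed from that of the 7-week array by 0.00 on X. A different response of dim and bright probes is an unlikely explanation, since X regions stayed at -0.29 relative to autosomal regions in the same 20th of input level, against -0.04 to 0.05 in 1000 draws of such autosomal regions. The array holds no positioned probe on Y, all pools are labelled male, and no biological explanation was tested.

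The untreated 23-week array stood apart beyond X, in both channels. Over kept probes, input intensities correlated at r = 0.983 between the 7-week and DSS arrays, and at 0.916 and 0.911 between the 23-week array and these. For the immunoprecipitate these values were 0.974, 0.950 and 0.923. The interquartile range of log2 input was 1.80 at 7 weeks, 1.45 at 23 weeks and 1.93 after DSS, and that of the immunoprecipitate 3.29, 3.43 and 2.98. The 10 regions gained after DSS against both untreated arrays with scaling had a median difference of 0.50 in the immunoprecipitate and -0.25 in the input.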
